A study of Homo sapiens with 16 samples.

How the data were processed

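ChIP-seq was performed on cross-linked, sonicated chromatin with antibodies to OCT2 or OCA-B, per the labels' protocols. The samples were tonsil germinal centre and naive B cells sorted by FACS, the OCI-Ly7 line, and OCI-Ly7 with CRISPR interference and either control or POU2AF1 guides. Groups were taken from the sample titles. The submitters' processing notes name BWA, Picard and MACS2 and the GRCh38 build, and versions, roles and settings are not given in the sources used here. The authors deposited 1 narrowPeak list per ChIP sample and did not pool replicates, so each library's peaks were called alone. The 7 input samples were not used here, other than through whatever part they had in the authors' calls.

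Each list gives, as deposited by the authors, a position, a score, a fold enrichment, −log10 p and −log10 q at the summit, and the summit's distance from the peak start. The deposited fold is a ratio of the signal at the summit to the local background. In 5 lists (primary cells and unmodified OCI-Ly7) the deposited score was 10 times −log10 p and the lowest deposited −log10 p lay between 4.01 and 4.03. In the 4 CRISPR interference lists the deposited score was 10 times −log10 q and the lowest −log10 q lay between 1.30 and 1.37. The authors' threshold therefore lay on p in the former lists and on q in the latter, which bears on any comparison across them. The distance to the summit, deposited by the authors and of no other unit than bases, was used to place summits. Fold and −log10 p are the authors' own values of each peak and served to describe, rank or filter peaks within 1 list. Across lists they were used only through the background recovered from them.

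Peaks on chromosomes 1 to 22 and X were used, with XIST and TSIX left out of the gene table. The lists carry no read totals. Depth was described by solving each peak's fold, (pileup + 1) / (background + 1), and its Poisson −log10 p for pileup and background, keeping peaks with −log10 p under 100 and a pileup whole to within 0.02 reads. Between 81.9% and 99.2% of peaks per library were solved. That solved pileups are whole follows from this filter and is no support for the solution. The lowest background shared by several peaks, with the fragment length taken as the shortest called peak, gave 11.5 to 37.6 background reads per kb. The fragment length bears on them: with 199 bp, the median of the shortest peaks, in all libraries they were 10.1 to 28.3, and replicate 1 with POU2AF1 guides fell from 37.6, which rests on 72 bp and 12 peaks, to 13.6. These densities describe background coverage and are not read totals. For the OCA-B library of GCB 1 read was worth a pileup of 1.05, above 1, which the solution does not explain. Depth sets which weak sites pass a fixed threshold, so a site missing from a list was not detected at that depth and threshold, which does not show that it was unbound.

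Overlap meant at least 1 bp in common. A baseline for overlap was measured by moving the peaks of 1 list along each chromosome (20 circular shifts). Moved peaks fall on any sequence, near genes or not. A share above theirs therefore does not show that 2 lists share sites more than other lists do. Control regions were the merged regions with a peak in both control libraries, 51734 in all. Such a region was kept if a peak of the library with POU2AF1 guides overlapped it. For quintiles, peaks or regions were ranked on −log10 p (control regions on the mean rank in the 2 controls). Shares carry exact binomial (Clopper-Pearson) 95% intervals. The number of peaks under control and POU2AF1 guides was compared by a 2-sided exact permutation test on log peak numbers with the library as the unit, and other measures of these groups were not tested, as 2 against 2 libraries cannot give a p below 0.33 in an exact permutation test. The remaining comparisons had 1 library per group. The labels call the replicates of the cell line independent experiments.

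Genes came from a table of RefSeq genes of the GRCh38.p14 assembly, with 19970 protein-coding genes on the chromosomes used. Each summit was assigned to the nearest protein-coding gene interval within 50 kb, or to every gene that contained it. The design had planned distances to transcription start sites. The gene table holds no strand, so gene intervals and either gene end were used in their place. The planned search for the octamer and other DNA elements at summits needs a genome sequence and was not run, and positions within exons or introns were not given.

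There were 10 gene lists of 186 members, all matched by symbol: germinal centre B cell genes, naive B cell genes, plasma cell genes, B cell receptor signalling and B cell identity, MHC class II, CD40 and NF-kappaB response, cell cycle, T cell markers, myeloid markers and genes of unrelated tissues. The last 3 stand for other cell types. Gene families were H2B histone genes, other replication histone genes, immunoglobulin V segments and snRNA-type genes, with T cell receptor V segments added later as a comparator, and a member counted if a summit lay in it or within 500 bp. A list's share was set against 10000 random lists of protein-coding genes drawn from the same deciles of territory, the stretch from which a gene can receive summits. Percentiles from these lists describe these libraries and are not p-values. Kept shares of a list were set against control regions drawn from the same of 50 bins of control rank, and, as a second version, from the 100 regions nearest in rank on each side. A later version also matched the draws on OCA-B in the unmodified line. The share of replicate 2 peaks found in replicate 1 (0.458%) was at first a test of failed enrichment and was dropped, since 77 peaks cannot cover a large share of 7634.

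Genes were named by a rule. It took the genes of the top 10 peaks of each class of each comparison, ranked by the authors' −log10 p, with 1 peak per gene. It added 20 fixed genes (such as POU2AF1, BCL6 and EBF1) and, from each list, the 2 to 4 members with the strongest peak. The reference library was OCT2 in GCB. RGS13, TXNIP, S1PR1, JCHAIN, ELL2, SEC11C and the snRNA genes given as examples were chosen after their values were seen. The groups, main comparisons, gene lists, naming rule and other settings to try were fixed before the data were examined. The distances to gene intervals and gene ends, the rank-matched draws (set before their own outcome was seen), the T cell receptor V comparator, the strongest quintile, the weighting of recurrence over quintiles, the comparison by OCA-B at matched ranks and the common fragment length were added after.

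The alternatives were an overlap of at least 0.5 of the shorter peak, −log10 q of at least 5 or 10, the top 10000 peaks of each list, and regions bound in either control. Others left out each CRISPR interference library in turn, blocked on replicate number, weighted over quintiles of strength, widened the gene-end distance to 2.5 kb, took the top 5000 peaks, or assigned genes within 5 kb of either gene end.

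The steps were tested on simulated data. Overlap was right for all 3000 simulated peaks. The solution for pileup and background resolved 94.6% of 3947 simulated peaks, with 0 wrong among those resolved. In 200 simulated gene lists with no difference 97.5% lay within the central 95% of random lists, and a share raised from 40% to 85% was found in 99.5% of 200 lists. These lists held 20 genes, each positive or not, without territory deciles or several peaks per gene, so they tested the percentile step alone. The simulated pileups followed the same formulas as the solution and cannot show that these hold for the deposited lists. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.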

Results

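OCT2, the octamer-binding transcription factor encoded by POU2F2, and OCA-B, the B-cell coactivator encoded by POU2AF1 that joins OCT proteins on DNA, were mapped by ChIP-seq in human B cells. Chromatin came from sorted tonsil B cells of 2 kinds: germinal centre B cells (GCB), which divide and mutate their immunoglobulin genes in lymphoid follicles, and naive B cells (NB), which have not yet been activated by antigen. OCI-Ly7, a lymphoma line derived from germinal centre B cells, was profiled unmodified and in a form that carries dCas9-KRAB, a cleavage-dead Cas9 fused to a repressor domain that silences the gene its guide RNA points to (CRISPR interference). That form received either non-targeting guides (control) or guides against POU2AF1. The series held 16 samples, of which 9 had a peak list, and the 7 input samples were not used here. OCT2 in GCB, OCA-B in GCB, OCT2 in NB and each factor in unmodified OCI-Ly7 had 1 library each, so these comparisons had no replicate error and no test. Control and POU2AF1 guides had 2 OCT2 libraries each, which the labels give as independent experiments.

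On chromosomes 1 to 22 and X the authors' lists held 62292 OCT2 and 25614 OCA-B peaks in GCB, 37077 OCT2 peaks in NB, and 73999 OCT2 and 64521 OCA-B peaks in unmodified OCI-Ly7. With control guides OCT2 had 69698 and 65706 peaks, and with POU2AF1 guides 77 in replicate 1 and 7634 in replicate 2. Peak lists carry no read totals. The background read density recovered from each list's own statistics was 12.4 reads per kb for OCT2 in GCB, 11.5 for OCA-B in GCB and 26.2 for OCT2 in NB. It was 13.8 and 18.3 for OCT2 and OCA-B in unmodified OCI-Ly7, 14.8 and 13.9 in the controls, and 37.6 and 16.3 in replicates 1 and 2 with POU2AF1 guides. The density of replicate 1 rests on 12 peaks and on a fragment length of 72 bp, its shortest peak, and with 199 bp, the median over libraries, it was 13.6. Intervals on shares of peaks are exact binomial 95% intervals and cover counting error only.

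**Figure D1:**
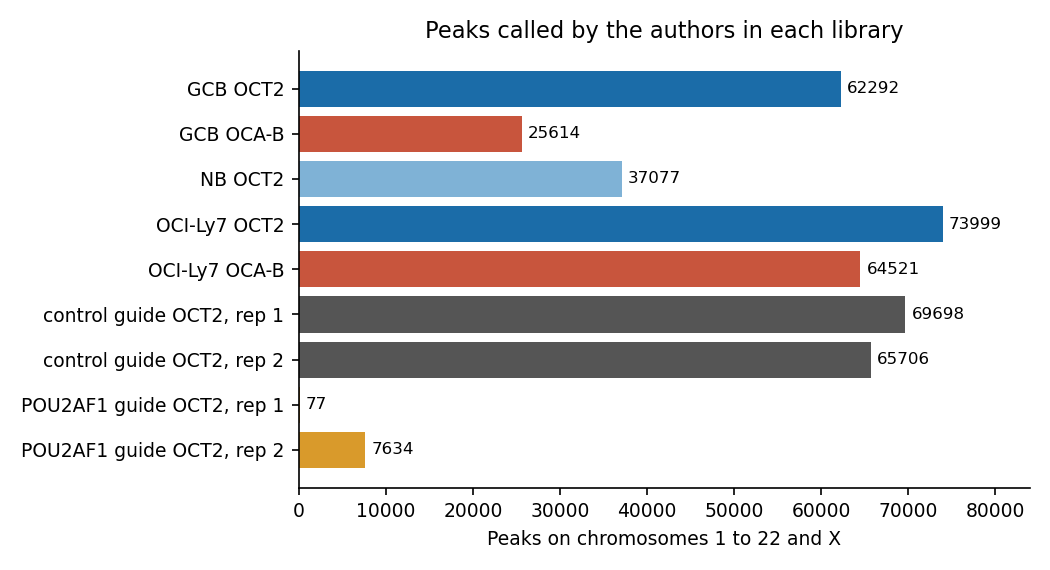
Number of peaks on chromosomes 1 to 22 and X (horizontal axis) in each of the 9 libraries (1 bar per library). The bars of the libraries with POU2AF1 guides reach 77 and 7634 peaks, and those with control guides 69698 and 65706.

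The first comparison asked how OCT2 binding differs between naive and germinal centre B cells. Of the GCB OCT2 peaks, 20525 (32.9%, interval 32.6 to 33.3) had an NB OCT2 peak, and 56.1% of the NB peaks (55.6 to 56.6) had a GCB peak. With the top 10000 peaks of each list the shares were 55.4% and 56.5%, where equal length makes both directions alike. The strongest sites were the shared ones: 76.5% of the strongest quintile of GCB peaks had an NB peak, against 10.7% of the weakest quintile. All 25 genes of the germinal centre list had an OCT2 peak in both cell types, and 283 of their 334 regions bound in a single cell type were bound in GCB alone (84.7%), which lay at the 97.4th percentile of random lists of matched genes (median 72.6%), inside their central 95%. Genes of the naive B cell list leaned the other way, with 86 of 188 such regions in GCB alone (45.7%, percentile 0.21 among random lists).

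Among the germinal centre genes, MYBL1, a transcription factor of germinal centre cells, had 15 OCT2 peaks in GCB and 4 in NB. RGS13, a regulator of G-protein signalling, had 27 and 6, KLHL6 had 24 and 7, and PAG1 had 33 and 13. MEF2B, which activates BCL6, had 7 peaks in GCB and 1 in NB. S1PR2, the receptor that confines cells to the follicle, had 7 and 2. Of the naive list, KLF2, a transcription factor of resting lymphocytes, had 1 OCT2 peak in GCB and 8 in NB, and TXNIP had 2 and 8. S1PR1, the receptor for leaving lymphoid tissue, had 7 and 12, and BANK1 had 27 and 39. BTG1, with 26 and 24 peaks, and CD44, with 18 and 15, differed less in number. The GCB list was the longer as a whole, with 62292 peaks against 37077 in NB. Counts per gene, here and in the next paragraphs, were not scaled for this. BACH2, a repressor that holds back plasma cell differentiation, had 65 and 49 peaks.

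B cell identity genes were bound in both cell types. All 24 genes of the list for B cell receptor signalling and B cell identity had OCT2 peaks in GCB and in NB, and 75.8% of their regions bound in a single cell type were bound in GCB alone (percentile 68.8). EBF1 had 86 OCT2 peaks in GCB and 60 in NB, PAX5 had 24 and 20, MS4A1 (CD20) had 12 and 8, and BTK had 4 and 5. CD79A had 3 and 2 and CD79B had 3 and 4. SPIB had 4 and 3, TCF3 had 8 and 8, and PLCG2 had 36 and 26. The genes of the OCT factors and their coactivator carried peaks themselves: POU2F1 had 23 OCT2 peaks in GCB and 8 in NB, POU2F2 had 7 and 5, and POU2AF1 had 11 and 6. All 13 MHC class II genes were bound in both (67.4%, percentile 45.7), among them CIITA, the master regulator of the group, with 14 and 17 peaks, HLA-DQA1 with 19 and 15, and CD74 with 6 and 4. Of the 17 genes of the CD40 and NF-kappaB response, 16 had a peak in GCB and 17 in NB (68.0%, percentile 38.9), MYC had 8 and 5 peaks, and REL had 17 and 11.

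Plasma cell genes had a share nearer to that of the naive list, though inside the central 95% of random lists. Of these genes 12 of 15 had a peak in each cell type, and 27 of the 52 regions bound in a single cell type were in GCB alone (51.9%, percentile 5.20). PRDM1, which drives plasma cell differentiation, had 10 peaks in each. IRF4, which acts in the same step, had 0 peaks in GCB and 2 in NB. Cell cycle genes had peaks at 13 of 18 members in GCB and 12 in NB (88.6% in GCB alone, 31 of 35 regions, percentile 96.4). Markers of other cell types served as a background: T cell markers had peaks at 11 of 18 members in GCB and 8 in NB (78.8%, percentile 79.8), and myeloid markers at 8 and 3 of 16 (84.2%, percentile 89.2). Genes of unrelated tissues had peaks at 7 and 4 of 20 members (85.7%, 6 of 7 regions, percentile 95.3), fewer than in random lists, whose medians were 11 and 10 members.

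By peak strength, the shared sites were led by CSF2RA (chromosome X, 1289432 to 1290480), BLCAP (chromosome 20, 37527855 to 37528535), ZBTB4, ADNP, TRMT112 and SOS1. Sites of GCB alone were led by NDUFAF6 (chromosome 8, 95080208 to 95080842), MRPL4, MREG, ERC2 and TMEM154. Those of NB alone were led by DTHD1 (chromosome 4, 36303332 to 36303897), ALDH16A1, KLF2 (chromosome 19, 16326056 to 16326884, inside the gene) and TUBA1A. Coordinates are those of the GRCh38 build.

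Gene families with octamer elements known in their promoters (H2B, snRNA and immunoglobulin V genes) were counted beside all protein-coding genes, of which 52.3% in GCB and 47.2% in NB had an OCT2 peak by the same rule. The rule takes a summit anywhere in the gene, so a longer gene offers a larger target. Families and protein-coding genes were not matched on length, so their shares do not rank them by binding. Of 19 H2B histone genes, 17 had an OCT2 peak in GCB and 17 in NB. Of 26 snRNA-type genes, 20 had one in GCB and 23 in NB. Other replication histone genes had peaks at 37 and 38 of 51 members. Among 133 immunoglobulin V segments, 45 had a peak in GCB (33.8%) and 24 in NB (18.0%), and all 24 were among those bound in GCB. T cell receptor V segments had peaks at 14 and 7 of 104.

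Both overlaps between GCB and NB lay below that of the 2 control libraries of OCI-Ly7, where 76.7% and 82.3% of peaks recurred, which is the only replicate overlap in these data and comes from another cell type. The control lists also have their threshold on q and are closer in length (69698 and 65706 peaks). Those of GCB and NB have it on p and differ more (62292 and 37077). Peaks moved along the chromosomes overlapped in 1.05% and 1.73% of cases. With 1 library per cell type, a difference between cell types and a difference between libraries cannot be separated.

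The region between BCL6, the master repressor of germinal centre B cells, and LPP was then examined, since it holds the BCL6 locus control region. This interval of 408 kb (chromosome 3, 187745469 to 188153020, between the genes) held 68 OCT2 and 44 OCA-B peaks in GCB and 30 OCT2 peaks in NB. Windows of the same length held on average 8.37, 3.45 and 4.99 peaks, and the interval lay above 99% of windows for each library. Of the 68 GCB OCT2 peaks, 18 had an NB peak, 43 had OCA-B and 49 recurred in unmodified OCI-Ly7, which held 73 OCT2 and 65 OCA-B peaks there. The strongest OCT2 peak of the interval in GCB lay at 187900223 to 187902689 (authors' fold enrichment 53.4). BCL6 itself was nearest to 16 OCT2 peaks in GCB and 14 in NB.

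**Figure D2:**
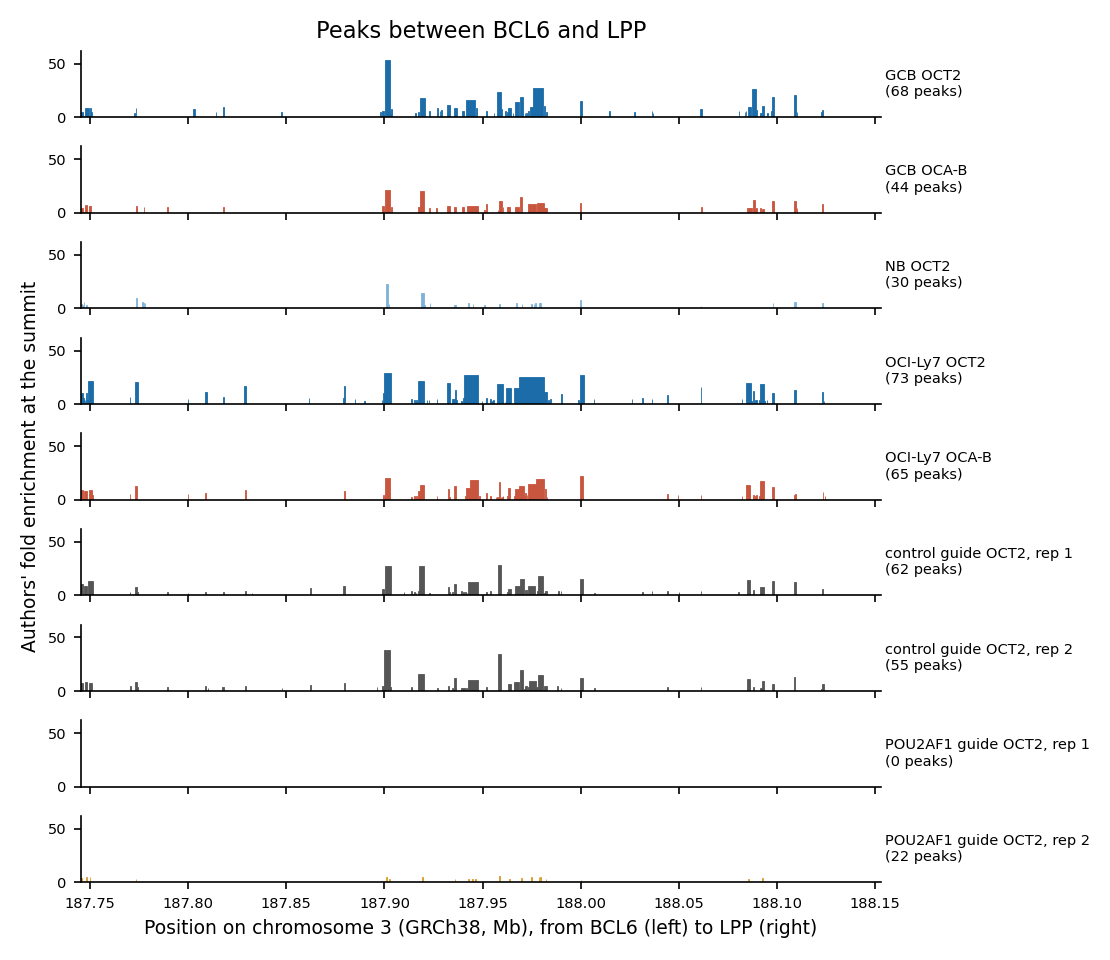
Peaks between BCL6 and LPP (horizontal axis: position on chromosome 3 in Mb, GRCh38; vertical axis: the authors' fold enrichment, relative to each library's own background and so not comparable in height between libraries). GCB held 68 OCT2 peaks, NB 30, the controls 62 and 55, and the libraries with POU2AF1 guides 0 and 22.

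The next comparison placed OCA-B on the OCT2 map of GCB. OCA-B lay largely on OCT2: 83.3% of the 25614 OCA-B peaks (82.9 to 83.8) had an OCT2 peak, and 35.3% of OCT2 peaks (35.0 to 35.7) had OCA-B. With the top 10000 peaks of each list the shares were 64.3% and 64.2%. Sites already bound by OCT2 in naive cells carried it most often, with OCA-B at 73.1% of GCB OCT2 peaks that had an NB peak (15013 of 20525) and at 16.8% of those without (6997 of 41767). That is a ratio of 4.37, or 2.41 when weighted over quintiles of peak strength. Peaks were not matched on width, and a wider peak can more easily overlap both an NB peak and an OCA-B peak. In the strongest quintile the shares were 90.6% and 66.8%, and in the weakest 39.5% and 6.64%. NB peaks that were not bound in GCB had a GCB OCA-B peak in 8.83% of cases.

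The share of OCT2 peaks with OCA-B was set beside random lists for each gene list, without matching on OCT2 strength. At genes of B cell receptor signalling and B cell identity 56.7% of GCB OCT2 peaks had OCA-B (245 of 432), against a median of 37.0% in random lists (percentile 99.7). CD40 and NF-kappaB genes had OCA-B at 58.4% (percentile 96.1), naive B cell genes at 50.3% (96.6) and germinal centre genes at 49.9% (97.9). MHC class II genes reached 53.1% (78.3), plasma cell genes 49.0% (84.7) and cell cycle genes 44.6% (52.8). In the lists of other cell types, T cell markers had 54.1% (20 of 37 peaks, 91.3), myeloid markers 30.4% (14.1) and genes of unrelated tissues 25.0% (3 of 12 peaks, 6.50).

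OCA-B lay at 6 of the 7 OCT2 peaks of S1PR2, 12 of 16 at BCL6, 15 of 24 at PAX5, 44 of 86 at EBF1 and 28 of 65 at BACH2. It lay at 8 of 12 at MS4A1, 3 of 3 at CD79B, 2 of 3 at CD79A, 4 of 6 at CD74, 5 of 7 at POU2F2 and 4 of 11 at POU2AF1. MYBL1 had it at 6 of 15, MEF2B at 3 of 7, PRDM1 at 4 of 10, MYC at 4 of 8, POU2F1 at 8 of 23, SPIB at 1 of 4 and BTK at 0 of 4. The strongest joint sites, ranked by OCA-B, were assigned to SOS1 (chromosome 2, 39140617 to 39142384), DAAM1, OSBPL10, CFAP299, BACH2 (chromosome 6, 90285206 to 90288617) and MBNL1. The strongest OCT2 peaks without OCA-B lay at CSF2RA, RNF169, AHCY and TNKS1BP1.

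**Figure D3:**
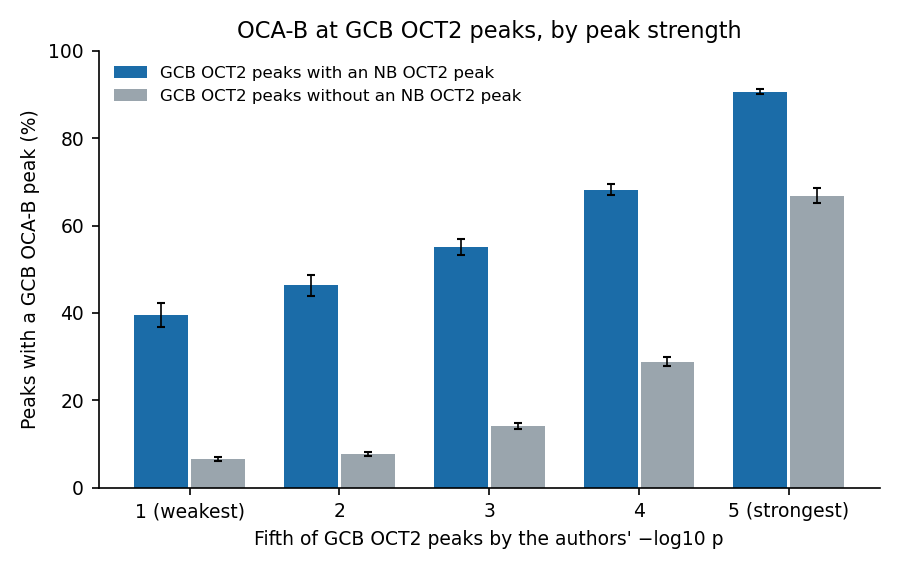
Percent of GCB OCT2 peaks with a GCB OCA-B peak (vertical axis) in quintiles of GCB OCT2 peaks by the authors' −log10 p (horizontal axis), with exact binomial 95% intervals. In each quintile the peaks with an NB OCT2 peak stand higher, from 39.5% against 6.64% in the weakest to 90.6% against 66.8% in the strongest.

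The lymphoma line was compared in the same way. OCA-B and OCT2 overlapped widely in unmodified OCI-Ly7, where 73.2% of OCA-B peaks (72.8 to 73.5) had OCT2 and 62.2% of OCT2 peaks (61.9 to 62.6) had OCA-B. Among the strongest quintile of OCT2 peaks 97.9% had OCA-B, and among the weakest 29.8%. All 14 OCT2 peaks of S1PR2 had OCA-B, as did all 9 of CD79B, 8 of CD74 and 7 of SPIB and 18 of 19 at MEF2B. BTK had OCA-B at 10 of 12, PAX5 at 26 of 36, EBF1 at 35 of 67, BACH2 at 33 of 75 and MS4A1 at 5 of 13. The strongest joint sites, ranked by OCA-B, lay near CD300LB (chromosome 17, 74513771 to 74515250), PIM2, PRRC2A, FAM117A, LENG9 and MALT1. The strongest OCT2 peaks without OCA-B were nearest to GCG, HAPSTR1, DISC1 and OSCAR. Shares at germinal centre genes (64.4%), naive genes (58.9%) and B cell identity genes (66.2%) lay between the 32.4th and 73.2nd percentiles of random lists. Of the remaining lists, only genes of unrelated tissues lay above the 95th percentile (9 of 10 peaks). The 2 factors came from 1 library each, and moved peaks overlapped in under 2% of cases. That gap is not particular to this pair. Of NB OCT2 peaks, 49.0% had an OCA-B peak in OCI-Ly7, against 1.70% when moved.

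OCI-Ly7 was also set against the primary cells. Of the GCB OCT2 peaks 41.7% (41.3 to 42.1) recurred in OCI-Ly7, and of the GCB OCA-B peaks 66.1% (65.6 to 66.7). With the top 10000 peaks of each list the order turned, at 44.4% for OCT2 and 41.4% for OCA-B. GCB OCT2 sites that NB shared recurred in 75.1% of cases and the others in 25.3%, while GCB OCT2 sites with OCA-B recurred in 73.8% and those without in 24.2%. Recurrence went with strength, from 19.1% in the weakest quintile to 80.7% in the strongest. Weighted over quintiles the contrasts were 67.1% against 31.8% for NB and 65.9% against 31.8% for OCA-B. Here too peaks were not matched on width. Against random lists, recurrence ranked highest at B cell receptor signalling and B cell identity genes (63.2%, percentile 98.2) and germinal centre genes (58.6%, percentile 96.3). It was 50.3% at naive genes (73.8), 59.2% at plasma cell genes (83.8), 43.0% at MHC class II genes (25.0), 49.7% at CD40 and NF-kappaB genes (44.6) and 62.5% at cell cycle genes (75.6). T cell markers had 51.4% (51.3), myeloid markers 47.8% (33.3) and genes of unrelated tissues 41.7% (28.1). All 7 GCB peaks of POU2F2 and 6 of 7 at S1PR2 and at MEF2B recurred. RGS13 kept 17 of 27, BACH2 26 of 65, EBF1 37 of 86 and BANK1 3 of 27. IRF4, which had 0 GCB peaks, had 19 OCT2 peaks in OCI-Ly7. The strongest GCB OCT2 peaks not found in OCI-Ly7 lay at NDUFAF6, SERPINA12, SH3RF1 and IRF2, and the strongest found there alone were nearest to REG3G, SLC4A5, LRRTM4 and CABLES1. Overlap of the control libraries with unmodified OCI-Ly7 was 65.9% and 67.3%.

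In GCB and in unmodified OCI-Ly7 OCA-B lay at gene ends more often than OCT2 did. Within 1 kb of either end of a protein-coding gene lay 24.6% of GCB OCA-B summits and 12.6% of GCB OCT2 summits, with 18.1% for OCT2 in NB. In unmodified OCI-Ly7 the shares were 22.3% for OCA-B and 14.7% for OCT2. Control libraries had 15.7% and 16.0%, and the libraries with POU2AF1 guides 0% (0 of 77) and 22.8%. With 2.5 kb the shares of lists other than replicate 1 lay between 20.1% and 33.9%, and among the top 5000 peaks of each list the shares within 1 kb were 9.04% for OCT2 and 21.3% for OCA-B in unmodified OCI-Ly7, 12.9% and 21.8% in GCB, and 23.4% for OCT2 in NB. Moved summits lay there in 1.56% to 2.73% of cases. The gene table gave no strand, so starts and ends of genes were not told apart, and exons and introns were not resolved.

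The last comparison asked what silencing POU2AF1 does to OCT2 binding. At the targeted gene itself OCT2 had 14 and 9 peaks in the control libraries and 0 in each library with POU2AF1 guides. None of its 8 regions bound in both controls had a peak with POU2AF1 guides. Over all such regions 0.00580% had a peak in replicate 1 and 13.7% in replicate 2. The loss at 8 regions therefore does not set this gene apart. OCT2 peaks do not measure POU2AF1 expression, so the silencing could not be checked from these files. OCT2 peaks became few across the genome, from 69698 and 65706 to 77 and 7634, a ratio of geometric means of 88.3 (2 against 2 libraries). The 2-sided exact permutation test gave p = 0.33, the smallest value that this design allows, so it cannot reach 0.05. The size rested on replicate 1: without it the ratio was 8.86, and without replicate 2 it was 879. At −log10 q of at least 10 the ratio was 157.

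Of the 51734 regions bound by OCT2 in both controls, 3 (0.00580%) had a peak in replicate 1 with POU2AF1 guides and 7063 (13.7%, 13.36 to 13.95) in replicate 2, a mean of 6.83% ± 9.65 (SD, n = 2). Of regions bound in either control a mean of 4.50% was kept. Control peaks recurred in the other control in 76.7% and 82.3% of cases. Nearly all replicate 2 peaks were control sites (98.4% overlapped a peak of either control), against 20 of the 77 in replicate 1. Replicate 2 kept 50.6% of the strongest quintile of control regions, 12.5% of the next and 0.406% of the weakest. Of the 7634 replicate 2 peaks, 61.3% and 61.7% lay among the 7634 strongest peaks of each control, and so did 65.9% and 64.3% of the 7634 strongest peaks of unmodified OCI-Ly7. Of the 7634 strongest peaks of control 2, 83.1% lay among those of control 1. Values for gene groups come from replicate 2, as replicate 1 kept 0 regions at each gene group named.

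snRNA and histone genes kept OCT2. All 21 snRNA-type genes bound in both controls, such as RN7SK, RMRP and RNU12, had a peak in replicate 2, as did 14 of 15 H2B genes and 25 of 29 other replication histone genes. Over all members, replicate 2 had peaks at 23 of 26 snRNA-type genes (22 and 21 in the controls). It had them at 34 of 51 other replication histone genes (31 and 29) and 14 of 19 H2B genes (15 and 16). Some members thus had a peak in replicate 2 but not in both controls. Immunoglobulin V segments kept 20 of 67 and T cell receptor V segments 2 of 16, against 3597 of 12068 protein-coding genes, which were not matched on gene length. Immunoglobulin V regions were kept in 27.6% of cases and regions matched on strength in a median of 35.5% (percentile 2.55, or 3.02 with the nearest ranks and 1.87 when matched on OCA-B too). By strength, the leading regions kept lay at H2AC6 (chromosome 6, 26122316 to 26126482), H2AJ, ERC2, FOSB, H2BC21 and H2BC26. The strongest regions lost from both replicates lay at STRBP (chromosome 9, 123233545 to 123235866), AK5, FNBP1, CDKN2C and CRYBA4, and a region inside PAX5 (chromosome 9, 37004068 to 37005171) was among the top 10. Against control regions matched on strength, snRNA-type and histone regions together were kept in 74.6% of cases (53 of 71) and the matched regions in a median of 59.2% (95% of draws between 52.1 and 66.2). OCA-B lay at 97.2% of them in the unmodified line, and draws matched on OCA-B as well had a median of 60.6% (53.5 to 67.6). Taken alone, the other replication histone regions stood above their range (78.9% against 55.3%). A region near genes of 2 families counts in both: 24 H2B, 38 other histone and 24 snRNA-type regions made up the 71 regions. The excess can therefore not be assigned to 1 family. The draws were not matched on region width. H2B regions (66.7% against 58.3%) and snRNA-type regions (91.7% against 83.3%) stayed within their ranges. Whether reads at histone genes are shared between similar copies could not be checked, as the lists carry no reads.

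**Figure D4:**
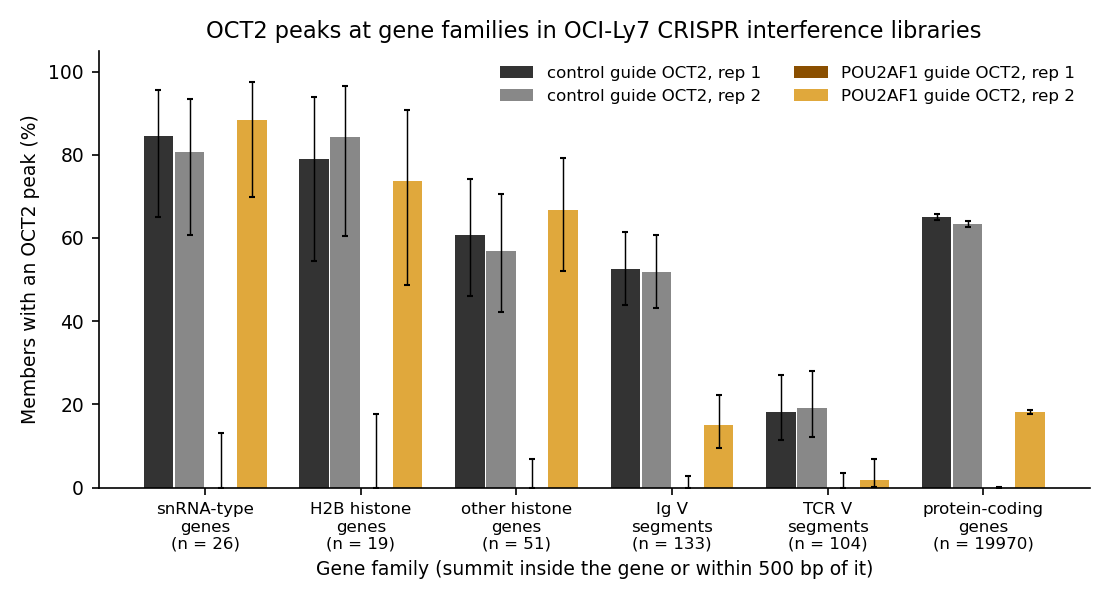
Percent of family members with an OCT2 peak inside the gene or within 500 bp of it (vertical axis) for each gene family (horizontal axis) in the 2 control libraries and the 2 libraries with POU2AF1 guides, with exact binomial 95% intervals. In replicate 2 snRNA-type genes stand at 88.5% and protein-coding genes at 18.2%, and in replicate 1 all families stand at 0%. Protein-coding genes were not matched to the families on gene length.

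B cell gene lists kept OCT2 at shares within the range of control regions matched on strength. Replicate 2 kept 18.1% of germinal centre gene regions (50 of 277, matched median 18.1%), 17.4% of naive (17.4%), 20.0% of plasma cell (17.1%) and 19.2% of B cell identity gene regions (20.1%). MHC class II regions were kept in 16.4% of cases (18.0%), CD40 and NF-kappaB in 11.6% (10.5%) and cell cycle in 14% (14%). T cell markers kept 15.7% (19.6%), myeloid markers 11.8% (11.8%) and genes of unrelated tissues 4 of 10 regions, above the 0% to 30% that held 95% of matched draws. CD79B kept 3 of 3 control regions, CD74 2 of 2, BCL6 5 of 13, PRDM1 3 of 8, BTK 3 of 8 and MS4A1 2 of 6. EBF1 kept 11 of 52, POU2F1 4 of 22, PAX5 4 of 24, MYBL1 2 of 7 and BACH2 2 of 25. At POU2F2 and MEF2B 1 region was kept, of 7 each, and S1PR2 kept 1 of 9. SPIB, MYC, IRF4 and CD79A kept 0 of 4, 6, 5 and 2. Between BCL6 and LPP 17 of 44 regions remained.

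Sites with OCA-B in unmodified OCI-Ly7 kept OCT2 more often than sites without, at 19.3% against 2.97%, a ratio of 6.50 (1.97 when weighted over quintiles of control strength, and 1.68 at matched ranks in 50 bins). In the strongest quintile the shares were 52.7% and 26.2%, or 41.9% and 26.2% at matched ranks, as regions with OCA-B ranked higher within it. Replicate 1 kept 0 of 33867 regions with OCA-B and 3 of 17867 without, too few to read a direction. Regions bound in NB were kept in 27.0% of cases and regions bound in GCB but not NB in 10.8%, a ratio of 2.49 (1.61 over quintiles). The weightings did not match regions on width, and a wider region can more easily overlap peaks of several lists. None of these shares had a test, as a single library gave them.

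**Figure D5:**
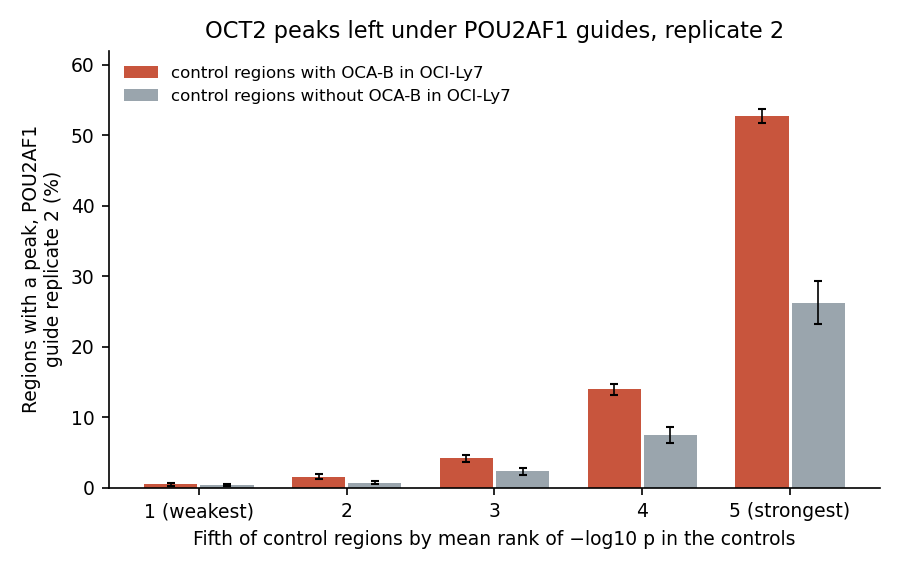
Percent of control regions with an OCT2 peak in replicate 2 with POU2AF1 guides (vertical axis) in quintiles of control regions by strength (horizontal axis), with exact binomial 95% intervals. In the strongest quintile 52.7% of regions with OCA-B and 26.2% of those without had a peak.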

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

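The tests of failed enrichment in replicate 1, of reads shared between gene copies, of nonspecific signal at snRNA and histone loci, of shallower sequencing of the naive library, and the draws matched on OCA-B, were chosen only after the result was seen.

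Of the list of replicate 1 with POU2AF1 guides, 41.7% lay outside chromosomes 1 to 22 and X, on sequences left out of all comparisons. For replicate 2 the share was 2.08%. In the control libraries it was 0.270% and 0.353%, and the excess over these drew attention to both lists.

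Both libraries with POU2AF1 guides had few OCT2 peaks, which loss of OCA-B or a weaker ChIP could each bring about. Shallower sequencing is argued against in replicate 2: rescaled to its background, 95.1% of control 2 peaks (the lower of the controls) would still pass its weakest called p. Only 10.9% of them were found. At the background and fragment length of replicate 1 37.4% of control 2 peaks would pass, and 0.0289% were found. That background rests on 12 peaks and on a fragment length of 72 bp, in a list with 41.7% outside chromosomes 1 to 22 and X. For replicate 1 the values argue against shallower sequencing only if that background holds. Failed enrichment in replicate 1 cannot be told apart from a loss of OCT2. At a peak of either control lay 26.0% of its 77 peaks. Moved peaks reached at most 3.90% at each control taken alone. Lying above moved peaks cannot tell OCT2 sites from other signal that recurs between libraries. The share of 26.0% was below 50%. That bound of 50% was set after the result was seen, so falling below it decides nothing. Of the 77, 19 lay on control 2 peaks and 4 on control 1 peaks, and 37 on replicate 2 peaks but 0 on peaks of the unmodified line. Weaker enrichment at every site alike remains open for the replicate 2 list as a whole. A mean of 61.5% of its peaks lay in equally long lists of the strongest control peaks. That is close to the 65.1% of the unmodified line though below the 83.1% of control 2 in control 1, as when the strongest sites alone pass the threshold. At snRNA and histone regions together 74.6% were kept, against at most 66.2% in 95% of matched draws. Taken alone, snRNA-type and H2B regions stayed within their ranges. The draws were not matched on region width, so the pooled share does not exclude such weakening. An effect of OCA-B on OCT2 binding stays open too, as the labels' guides and the state of each ChIP go together in 2 libraries and POU2AF1 expression was not measured.

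snRNA and histone regions were kept in replicate 2. Of these regions 74.6% were kept, and 95% of draws matched on control rank lay between 52.1% and 66.2%. The range was 54.9% to 67.6% with the nearest ranks. It was 53.5% to 67.6% when matched on OCA-B too, which 97.2% of these regions carried. Control rank alone does not account for this share, but the draws were not matched on width. A wide region can overlap a peak more easily, and the widths of these regions and of their matched draws were not compared. A loss of enrichment at every site alike is therefore not excluded. Reads shared between similar gene copies stay open, as the lists carry no reads to check this. Of the families taken alone, only the other replication histone regions stood above their range, and some regions count in 2 families. Of the 7 single-copy snRNA-type genes 100% were kept, but regions at such genes (87.5%) stood no higher than matched ones (87.5%). Nonspecific signal at these loci could not be decided from replicate 1, which had 0 peaks at them. Whether OCT2 needs OCA-B at these genes was not tested and stays open.

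Naive B cells had fewer OCT2 peaks than germinal centre B cells. Shallower sequencing of the naive library is argued against, as its background read density was 2.11 times that of the germinal centre library (2.23 times with a common fragment length). Weaker enrichment of the naive library cannot be told apart from a difference between the cell types: 23.5% of the strongest quintile of germinal centre peaks were missing from the naive list, between the 10% and 30% set as bounds, and 1 library stood for each cell type. A biological difference in OCT2 occupancy remains open and untested for the same reason.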

How the results depend on the processing

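The strongest quintile of GCB peaks, the use of gene ends and gene intervals in place of start sites, recurrence weighted over quintiles and the kept ratio at matched ranks were tests chosen only after the data were seen. Where no cause of a shift is given, the cause was not tested.

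Requiring 0.5 of the shorter peak lowered each overlap, since it is the stricter rule: GCB OCT2 in NB to 30.5%, NB in GCB to 52.3%, GCB OCA-B with OCT2 to 79.2%, GCB OCT2 with OCA-B to 33.0%, OCI-Ly7 OCA-B with OCT2 to 70.6%, OCI-Ly7 OCT2 with OCA-B to 60.0%, and GCB OCT2 and OCA-B in OCI-Ly7 to 38.4% and 62.3%. At −log10 q of at least 5 the shares, in that order and without NB in GCB (56.2%, within its interval), were 36.4%, 84.5%, 36.5%, 74.5%, 61.8%, 45.5% and 67.3%. With the top 10000 peaks of each list they were 55.4%, 64.3%, 64.2%, 68.8%, 68.5%, 44.4% and 41.4%, with NB in GCB at 56.5%, so that the order of OCT2 and OCA-B in recurrence in OCI-Ly7 turned. Lists of equal length make both directions of an overlap alike. In the strongest quintile of GCB peaks 76.5% had an NB peak.

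The ratio of OCA-B shares at OCT2 sites shared with NB over the others was 2.41 over quintiles of strength, so part of it went with strength, 4.04 at −log10 q of at least 5 and 4.69 with 0.5 of the shorter peak. The kept ratio of regions with OCA-B over those without fell to 1.97 over quintiles of control strength, and to 1.68 at matched ranks in 50 bins, for the same reason. It was 6.50 without replicate 1 and 0 without replicate 2, where 3 kept regions are too few to read a direction. Recurrence ratios in OCI-Ly7 fell from 2.97 to 2.11 for NB and from 3.05 to 2.07 for OCA-B over quintiles. None of these weightings matched peaks or regions on width. The mean kept share lay between 0.00580% and 13.7% when each library was left out, and the ratio of peak numbers between 8.86 and 879, without replicate 1 and without replicate 2 with POU2AF1 guides. That ratio was 106 and 157 at −log10 q of at least 5 and 10. With a replicate block the peak number ratio was 88.3 (exact sign-flip permutation p = 0.5, the smallest that 2 pairs allow) and the mean kept share 5.45%. The replicates share only a number, and whether same-numbered libraries deviate together could not be checked with 2 pairs.

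Within 2.5 kb of gene ends lay 20.1% of OCT2 and 33.4% of OCA-B summits in GCB, 26.7% in NB, 24.4% and 33.9% in unmodified OCI-Ly7, 23.8% and 24.5% in controls 1 and 2 and 29.2% in replicate 2 with POU2AF1 guides, more by construction. Among the top 5000 peaks the share within 1 kb was 21.8% for OCA-B in GCB, 23.4% in NB, 9.04% and 21.3% in unmodified OCI-Ly7, 12.4% and 13.5% in the controls and 21.5% in replicate 2.

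GCB-only shares of germinal centre and naive gene regions stayed within their intervals under both gene settings. Counts of list members with a GCB OCT2 peak stayed within 1.5 times for 10 of 10 lists at −log10 q of at least 5 and for 8 of 10 within 5 kb of gene ends, where T cell markers fell to 6 and unrelated genes to 3. The octamer alternatives were not run, for lack of a genome sequence. Depth and threshold limit weak sites most, and the 5 lists with a threshold on p and the 4 with one on q differ in this.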

Other observations

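No test was run for what follows, and the comparison of plasma cell genes between OCI-Ly7 and GCB was chosen only after the result was seen.

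OCA-B also had peaks where OCT2 had none. In GCB 4273 OCA-B peaks lacked an OCT2 peak, and 1304 of them (30.5%) had one in NB, which left 11.6% of all OCA-B peaks with OCT2 in neither cell type. The strongest lay at NEURL2 (chromosome 20, 45891006 to 45891442), 39 bp outside the gene, and at SMARCD2, a subunit of the SWI/SNF chromatin remodelling complex (chromosome 17, 63842672 to 63843036). JUN, an AP-1 transcription factor (chromosome 1, 58781889 to 58782405), had one inside the gene. Peaks of OCA-B without OCT2 recurred at 2 of these sites in unmodified OCI-Ly7, at chromosome 20, 45891101 to 45891433, there assigned to the neighbour CTSA, and at SMARCD2 (chromosome 17, 63842656 to 63843055). By strength, such peaks in OCI-Ly7 were led by SRCIN1, SH2D3A, the CTSA site and KAT5, a histone acetyltransferase. In the weakest quintile of GCB OCA-B peaks 66.7% had OCT2, and in the strongest 98.4%.

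Some plasma cell genes had more OCT2 peaks in unmodified OCI-Ly7 than in GCB. IRF4 had 19 OCT2 and 17 OCA-B peaks against 0 and 0, XBP1, a regulator of secretion, had 23 OCT2 peaks against 3, JCHAIN 21 against 3 and TENT5C 27 against 8. ELL2, with 0 against 7, and SEC11C, with 3 against 6, went the other way. Members of the list with a peak were nearly as many in both, 13 and 12 of 15, both above 97% of random lists, with 143 and 49 peaks. Among the other lists T cell markers had 73 against 37, cell cycle genes 107 against 56, germinal centre genes 537 against 423, B cell identity genes 538 against 432 and naive genes 207 against 199. MHC class II genes had 90 against 128, CD40 and NF-kappaB genes 137 against 149, myeloid markers 20 against 23 and genes of unrelated tissues 10 against 12. BANK1 had 4 in OCI-Ly7 and 27 in GCB. OCI-Ly7 and GCB are 1 library each, and a copy number change in the line would raise or lower such counts.

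The 77 peaks of replicate 1 with POU2AF1 guides had a median width of 88 bp, against 388 bp in each control and 296 bp in replicate 2. None lay inside a protein-coding gene. Only 14 lay within 50 kb of one, of which 8 were nearest to CWH43 and 6 to LOC124905368. Of the 77, 37 overlapped a replicate 2 peak, 19 a peak of control 2, 4 a peak of control 1 and 0 a peak of unmodified OCI-Ly7.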
